A study of Homo sapiens with 9 samples.

How the data were processed

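Total RNA from MDA-MB-231 cells, an established human breast cancer cell line, was sequenced in 9 libraries. Cells transduced with a control guide RNA gave 3 libraries (WT), and 2 clones in which FBXL12 had been knocked out gave 3 libraries each (KO1 and KO2). FBXL12 encodes an F-box protein, the part of an SCF ubiquitin ligase that recognises the substrate. Per the labels' protocols, RNA was extracted with an RNeasy column kit, had an RNA integrity number of 10 in each sample and was made into Illumina TruSeq libraries. The labels number the libraries 1 to 3 in each group and do not say whether these came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. A clone is derived from 1 cell, so the genotype itself was sampled in 2 clones against 1 control population.

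Each deposited table holds raw read counts per gene symbol, 61155 symbols in each library, in whole numbers without any normalization. Per the submitters' processing notes, Trim Galore and HISAT2 were used, and the genome builds hg38, GRCm38 and mm10 are named without a role; the symbols in the tables are human. Versions of these tools, the read counter, the annotation release, the treatment of reads that map to several places and the strand setting are not given in the sources used here. Reads of an antisense gene and its partner, or of near-identical copies of a gene, therefore cannot be told apart with certainty. Total counts ran from 52427841 to 97243363 per library, a ratio of 1.85. A gene with 0 counts in a library could lie at up to 3 counts, which is 0.0309 CPM (counts scaled by the library total, as by the cpm function) in the deepest and 0.0572 CPM in the shallowest; such floors cover counting error only.

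Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes with low counts were removed with filterByExpr, which left 17759 genes, and libraries were scaled with TMM factors. A quasi-likelihood model with 1 mean per group was fitted over all 9 libraries with robust settings, so that the groups share 1 estimate of the spread. The contrasts were KO1 minus WT, KO2 minus WT, the mean of both clones minus WT, and KO1 minus KO2. The last contrast is also the test of whether the clones differ in their change from WT. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05, and adjusted p-values for genes come from this test unless another is named. The standard error of a log2 fold change was obtained by dividing its size by the square root of the quasi-F value. The biological coefficient of variation over all genes was 7.5%. No 2 libraries of a group agreed within sampling noise; chi-square per degree of freedom between libraries of a group ran from 6.12 to 31.3.

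Before the data were examined, 39 gene lists were fixed that cover DNA repair, the cell cycle, stress responses, inflammation, metabolism, breast epithelial state and markers of other cell types. Of their 932 genes, 930 matched a symbol in the tables, 50 of them by an older name. Lists with at least 5 tested members, 36 in all, were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over lists. Camera compares a list with the other genes. It was repeated with an estimated correlation, which allows for genes that vary together between libraries. The repeat was also stricter where the estimate did not exceed the preset. For unfolded protein response genes in KO1 the estimate was -0.006, yet the unadjusted camera p went from 8.1e-13 to 0.00023. A call lost in the repeat therefore does not by itself show that the members of a list vary together. The genes named were chosen by a rule fixed in advance. FBXL12 and FANCD2 were always named. Up to 12 rising and 12 falling genes with the greatest smaller change of the 2 clones were named among genes called in both, and up to 8 each way for each clone and for KO1 against KO2. All of these had a mean log2 CPM of at least 2 and libraries that did not overlap. Up to 4 members of each list were named by the smallest p. Some genes that the rule names are not reported here. Marker genes of other cell types and an antigen presentation gene were named after their values were seen.

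Gene positions, GC content and exon lengths were taken from GENCODE release 29 (GRCh38), which held 55772 of the symbols. A GC trend of each library was estimated by a lowess curve with a span of 0.3 on genes with a mean log2 CPM of at least 2 and removed through offsets. Along each chromosome, windows of 40 neighbouring protein-coding genes above the same limit were scored by how many genes lay on the same side of the median of all genes. A window was called shifted when at least 33 of its 40 genes did so, which is above the 95th percentile of the highest score over 500 random draws of signs, and overlapping shifted windows were joined into blocks. The GC correction and the block search were added after the data were seen. Plots were drawn with matplotlib 3.10.9.

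The tests were tried on simulated counts for the 17759 genes of the KO1 against WT comparison. Of 50 genes changed at each size, 22% were recovered at 1.2-fold, 58% at 1.5-fold, 72% at 2-fold and 100% at 4-fold. There were 12 false calls, 8.7% of all calls, and an unchanged clone gave 2 calls. A list shifted by 0.3 on the log2 scale was called with no other list, and 1 shifted chromosome region was found with no block in the unchanged clone. Genes were drawn independently of each other, so these runs do not test lists or stretches whose genes vary together between libraries. Far fewer genes were changed in them than were called in the data, so the shares recovered do not carry over to the data. Alternatives were other scalings, other filters on low counts, DESeq2 1.42.0, limma-voom, a block for the replicate number, fits of the compared groups only, thinning to the smallest total, leaving out each library, other thresholds, pooled clones and other list tests.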

Results

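RNA levels were measured in 9 libraries of MDA-MB-231 cells, 3 of control cells (WT) and 3 of each of 2 FBXL12 knockout clones (KO1 and KO2). Total counts were 97243363, 61685262 and 62860341 in WT, 77636004, 80043567 and 87084329 in KO1, and 52427841, 65630781 and 63119656 in KO2. Of 61155 gene symbols, 17759 were tested. The first principal component of log2 CPM (counts relative to the scaled library total) held 53% of the variance and set KO2 apart from the other groups. The second held 20.4% and set KO1 apart from WT. Transcripts of the mitochondrial genome made up 3.66% ± 0.16 of counts in WT (SD, n = 3), 3.52% ± 0.39 in KO1 and 4.81% ± 0.50 in KO2. CPM values are means of 3 libraries, and errors of log2 changes are standard errors.

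The series title names FANCD2 as a protein that FBXL12 degrades, and the first comparison was of the mRNA of both genes. FBXL12 mRNA was lower in both clones but was still detected in each of their libraries. Its level was 22.3 ± 0.999 CPM in WT (SD, n = 3), 9.64 ± 0.282 CPM in KO1 and 5.94 ± 0.542 CPM in KO2, which is 43.2% and 26.7% of WT. The log2 changes were -1.21 ± 0.08 in KO1 (95% interval -1.38 to -1.04, adjusted p = 2.6e-08) and -1.91 ± 0.08 in KO2 (-2.08 to -1.73, adjusted p = 7.3e-11). FANCD2, whose protein acts in the repair of DNA interstrand crosslinks, moved in opposite directions in the clones. It was at 68.4 ± 2.46 CPM in WT, 77.4 ± 2.08 CPM in KO1 and 57.7 ± 3.09 CPM in KO2. It rose by 0.18 ± 0.05 on the log2 scale in KO1 (interval 0.07 to 0.28, adjusted p = 0.0116) and its change in KO2 was -0.25 ± 0.05 (interval -0.35 to -0.14, adjusted p = 0.000794). The average over both clones was -0.03 (adjusted p = 0.569).

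FBXL12 (ENSG00000127452.8) lies on the minus strand of chromosome 19 at 9810267 to 9827816 (GRCh38). Its 20 neighbours had median log2 changes of -0.38 in KO1 and -0.78 in KO2, or -0.30 and -0.58 after removal of the GC trend of each library, where FBXL12 itself was at -1.04 and -1.73. FANCD2 lies on the plus strand of chromosome 3 at 10026414 to 10101930. It lay in a stretch of neighbouring genes with a median change of 0.16 in KO1 and in one with a median of -0.36 in KO2, both after that removal. The counts were per gene and do not show the edited sequence, and the guide RNA site is not given in the sources used here.

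**Figure D1:**
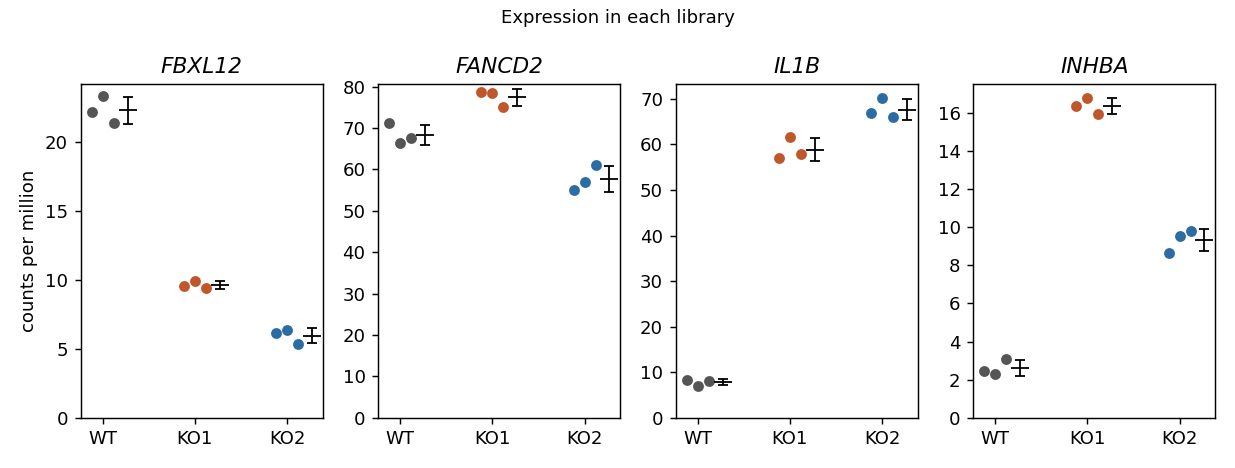
CPM of FBXL12, FANCD2, IL1B and INHBA in each of the 9 libraries (points), by group, with the group mean and SD beside them. FBXL12 is lower and IL1B and INHBA are higher in all 6 clone libraries than in the 3 WT libraries, and FANCD2 is highest in KO1 and lowest in KO2.

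The comparison of both clones with WT asks which transcripts differ from control cells in either clone alike. Several genes of secreted inflammatory proteins were among those that rose in both clones. IL1B, which encodes the cytokine interleukin-1 beta, went from 7.84 ± 0.718 CPM in WT to 58.9 ± 2.51 in KO1 and 67.7 ± 2.23 in KO2 (SD, n = 3). IL1A, which encodes interleukin-1 alpha, went from 3.33 to 12.8 and 17.7 CPM. The acute-phase gene SAA1 went from 1.22 to 9.90 and 5.18 CPM, and INHBA, which encodes a subunit of activin, from 2.59 to 16.4 and 9.34 CPM. PGM5, a gene of the phosphoglucomutase family, fell from 47.1 to 15.7 and 4.75 CPM, and the carboxypeptidase gene CPA4 from 41.9 to 20.4 and 18.1 CPM.

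Among genes called in both clones, 2674 changed in the same direction, 1328 up and 1346 down, and 1333 in opposite directions. The counts in each direction depended on the processing, with 1500 up and 1213 down by upper quartile, 1721 up and 1267 down after removal of the GC trend, and 1334 up and 723 down when genes in shifted stretches were also left out. Independent lists of these sizes would share 1526 in the same direction and 1527 in opposite ones; that calculation leaves out the shared control, from which part of the excess in one direction may come. Over all tested genes 60.3% had the same sign in both clones, against 66.6% in unchanged clones simulated with a shared control. Of the 2674 genes, 211 changed at least 2-fold in both clones, 141 up and 70 down. Other rising genes named by the rule had log2 changes in KO1 and KO2 of 2.27 and 2.73 for BCL2A1, an anti-apoptotic gene of the BCL2 family, and 1.76 and 1.80 for the complement gene C3. The chemokine gene CXCL3 changed by 1.59 and 2.10, ADGRE1 by 2.18 and 2.29, APCDD1L by 1.80 and 1.73, and APOL3 by 1.55 and 1.69. NRCAM, a neuronal cell adhesion gene, changed by 1.72 and 2.88, and SIRPA, which encodes a receptor for CD47, by 1.60 and 2.79. Reads of SAA1 and CXCL3 may be shared with close relatives.

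Other falling genes were MARCH1 (-1.50 and -2.29), the granzyme B inhibitor gene SERPINB9 (-1.57 and -1.30) and the arginase gene ARG2 (-1.25 and -1.04). The ribosomal protein gene RPS28 was at -0.97 and -1.62. CCDC124 was at -0.95 and -1.29, SCAND1 at -1.15 ± 0.30 and -1.32, and SSBP4 at -0.97 ± 0.29 and -1.33. FBXL12, RPS28, CCDC124 and SSBP4 lay in shifted stretches of chromosome 19 that were lower in each clone. SERPINB9 lay in stretches of chromosome 6 that were lower in both clones. After removal of the GC trend these had medians of -0.25 and -0.31, and SERPINB9 was at -1.62 and -1.35. After removal of the GC trend CCDC124 was at -0.63 and -0.86, SCAND1 at -0.85 and -0.96, and SSBP4 at -0.55 and -0.76, each still called. The KO1 calls of SCAND1 and SSBP4 were lost on leaving out some single libraries. Without WT replicate 2 they were at -0.98 and -0.81, without KO1 replicate 2 at -0.98 and -0.80, and without KO1 replicate 3 at -1.16 and -0.94, and in each of these fits they missed the adjusted p threshold. SSBP4 also lost its call at -1.07, -0.99 and -0.97 without WT replicate 1, WT replicate 3 and KO2 replicate 1.

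The average contrast called 7243 genes, 3614 up and 3629 down, of which 746 changed at least 2-fold. By upper quartile scaling 4012 were up and 3295 down. With the GC trend removed and genes in shifted stretches left out, 3154 were up and 2081 down. Across genes, which are not independent replicates, Pearson's r between the clones' changes was 0.229. Unchanged clones simulated with a shared control gave r = 0.494 from shared noise alone; the covariance of the changes was 0.1004 in the data and 0.0279 in the simulations. Both clones were set against the same 3 control libraries, and the genotype was sampled in 2 clones.

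**Figure D2:**
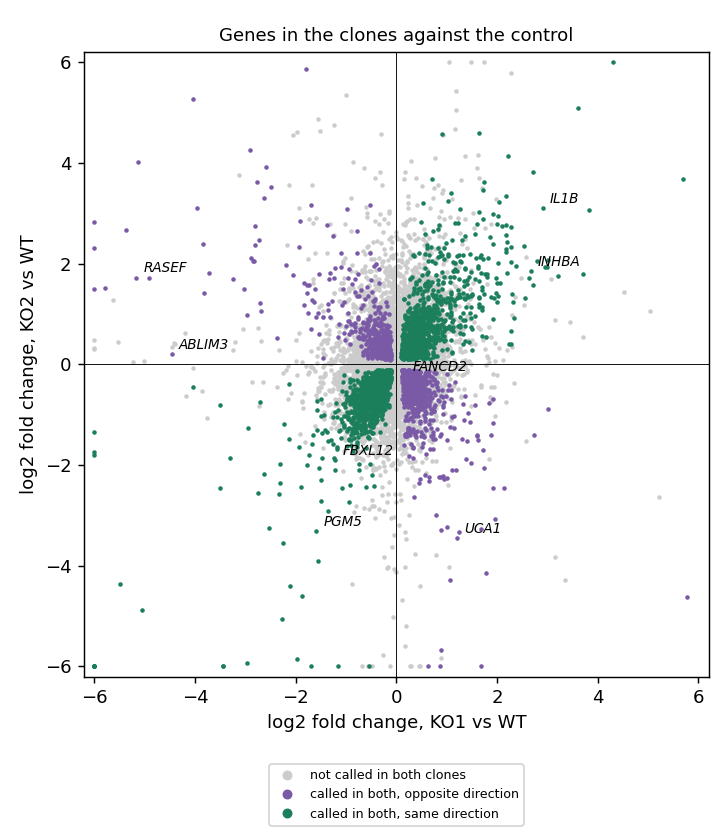
Log2 change in KO1 (horizontal) and in KO2 (vertical) for each tested gene, with values beyond 6 drawn at 6 and genes called in both clones in colour. Of the genes called in both, 2674 lie in quadrants of equal sign and 1333 in quadrants of opposite sign.

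Of 36 gene lists, 10 were called in the average contrast. The list of NF-kB targets and inflammatory cytokines had 20 of 32 tested members up, 2 down and 10 not past the threshold; adjusted over the list alone, 22 were up and 2 down. Its median log2 change was 0.41 (adjusted p = 4.5e-19, and 0.018 with an estimated correlation), and 11 members rose in each clone, IL1B, SAA1, IL1A and CXCL3 among them, while 1 fell in both and 5 moved in opposite directions. Cytosolic ribosomal protein genes had 43 of 60 members down, 0 up and 17 not past the threshold; adjusted over the list alone, 47 were down. Their median was -0.25 (adjusted p = 1.6e-17), but adjusted p = 0.293 with an estimated correlation. Of them 31 fell in each clone, among these RPLP0 (-0.33 and -0.51) and RPL10A (-0.34 and -0.52). RPL10A lies in stretches of chromosome 6 that were lower in both clones, and was at -0.20 and -0.39 after removal of the GC trend.

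Targets of NRF2, the regulator of the antioxidant response, together with aldehyde dehydrogenase genes had 15 of 24 members up, 1 down and 8 not past the threshold; adjusted over the list alone, 15 were up and 2 down. Their median was 0.36 (adjusted p = 3.6e-09, and 0.018 with an estimated correlation). The clones differed, with medians of 0.03 in KO1 and 0.63 in KO2. In both clones 7 members rose and 0 fell, while 3 moved in opposite directions. GCLM, a subunit of the enzyme that limits glutathione synthesis, went from 49.6 to 85.6 and 112 CPM. TXNRD1, which encodes thioredoxin reductase, changed by 0.28 and 0.80, the cystine transporter gene SLC7A11 by 0.43 and 0.70, and AKR1C3, whose reads may be shared with relatives, by 1.74 and 1.39. Interferon-stimulated genes had 25 of 40 members up, 6 down and 9 not past the threshold; adjusted over the list alone, 25 were up and 8 down. Their median was 0.31 (adjusted p = 9.5e-06, and 0.023 with an estimated correlation). OAS2 went from 5.49 to 10.6 and 18.2 CPM, OAS3 changed by 1.36 and 0.88, and HERC6 by 0.50 and 0.79, while 7 members moved in opposite directions in the clones. In KO1 alone the list was not called, with 17 up and 10 down (median 0.18; adjusted p = 0.39).

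The other 6 called lists lost their call with an estimated correlation. Replication licensing and fork genes had 0 members up and 16 of 41 down (16 adjusted over the list alone; median -0.09; adjusted p = 0.293 with an estimated correlation). Among them the DNA polymerase gene POLE was at -0.35 and -0.44, the licensing inhibitor gene GMNN at -0.45 and -0.67, and the DNA ligase gene LIG1 at -0.40 and -0.31. GMNN lies in stretches of chromosome 6 that were lower in both clones, with medians of -0.25 and -0.31 after removal of the GC trend. Nuclear-encoded oxidative phosphorylation genes had 4 up and 16 of 38 down (5 and 18 adjusted over the list alone; median -0.10; adjusted p = 0.742 with an estimated correlation). CYC1 was at -0.49 and -0.62 and UQCRC1 at -0.31 and -0.24; after removal of the GC trend CYC1 was at -0.15 and -0.20 and UQCRC1 at -0.01 in KO2, no longer called. Unfolded protein response genes had 12 up and 4 down of 20 (12 and 5 adjusted over the list alone; adjusted p = 0.187 with an estimated correlation), but in KO2 alone 4 were up and 8 down (median -0.04; not called). Matrix protease genes had 9 up and 4 down of 18 (9 and 4 adjusted over the list alone; adjusted p = 0.535 with an estimated correlation), and the cathepsin gene CTSL was at 0.85 and 1.28; in KO2 alone 6 were up and 8 down (median -0.02; not called). Mesenchymal genes had 10 up and 3 down of 19 (10 and 3 adjusted over the list alone; adjusted p = 0.293 with an estimated correlation), with CD44 at 0.41 and 0.78. Apoptosis regulators had 13 up and 5 down of 28 (14 and 5 adjusted over the list alone; adjusted p = 0.293 with an estimated correlation). They include the pro-apoptotic gene BAK1 at -0.69 and -0.52 and the death receptor gene TNFRSF10B at 0.32 and 0.23, beside the anti-apoptotic BCL2A1. BAK1 lies in stretches of chromosome 6 that were lower in both clones, and was at -0.51 and -0.31 after removal of the GC trend. Mesenchymal genes were not called in either clone alone, and licensing, oxidative phosphorylation and apoptosis genes not in KO2 alone. Without genes in shifted stretches, a test chosen after the data were seen, the calls of the unfolded protein response (median 0.12), matrix protease (0.20) and apoptosis (0.12) lists were lost. The matrix protease call was also lost with limma-voom (0.10), and that call (-0.04) and those of the apoptosis (0.13) and oxidative phosphorylation (-0.10) lists with a filter of at least 1 CPM in 3 libraries. The call of the oxidative phosphorylation list was also lost with upper quartile scaling (-0.08) and without WT replicate 1 (median -0.10), WT replicate 2 (-0.06), KO1 replicate 1 (-0.09), KO1 replicate 3 (-0.09) and KO2 replicate 3 (-0.08).

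KO1 was compared with WT to ask what differs in the first clone. Among the listed genes, 25 of 32 NF-kB targets and 15 of 20 unfolded protein response genes rose, and some other genes fell to a small share of their control level. LCP1, an actin-bundling gene, went from 5.27 to 30.8 CPM, and the interstitial collagenase gene MMP1 from 1101 to 2847 CPM. ABLIM3 fell from 77.2 to 3.51 CPM, and RASEF from 3.01 to 0.0829 CPM.

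KO1 had 6178 called genes, 3200 up and 2978 down, and 631 of these changed at least 2-fold, 333 up and 298 down. With the GC trend removed and genes in shifted stretches left out, 2553 were up and 1800 down. Rising genes named for this clone included C15orf48 (log2 change 2.28), SAP30L-AS1 (2.24, an antisense gene whose reads cannot be told from its partner's), MPZL2 (1.93), LCP2 (1.84), MMP3 (1.79) and ADAMTS9 (1.72). Falling genes included TENM1 (-3.24), FRMD3 (-2.82), FGF13 (-2.72), CCN3 (-2.36), BST2 (-2.20) and GLUL (-2.60), the gene of glutamine synthetase. GLUL had as few as 4 counts in a KO1 library, and its change ran from -3.03 to -2.22 when single libraries were left out.

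In KO1, 13 lists were called, and the calls of the NF-kB and unfolded protein response lists held with an estimated correlation (adjusted p = 0.00417 for each). NF-kB targets had 25 up, 1 down and 6 not past the threshold of 32 (26 up and 1 down adjusted over the list alone; median 0.78). Unfolded protein response genes had 15 up, 3 down and 2 not past the threshold of 20 (15 and 3 adjusted over the list alone; median 0.37). The chaperone gene HSPA5 was at 0.48, and HSP90B1 went from 840 to 1320 CPM. Matrix protease genes had 12 up and 1 down of 18 (median 0.50; adjusted p = 0.0581 with an estimated correlation). Basal keratins and markers had 6 up and 1 down of 12 (median 0.21; adjusted p = 0.0581 with an estimated correlation), with the integrin gene ITGA6 at 0.86. Ribosomal protein genes had 0 up and 45 down of 60 (median -0.28; adjusted p = 0.236 with an estimated correlation), oxidative phosphorylation genes 1 up and 25 down of 38 (adjusted p = 0.441 with an estimated correlation), and licensing genes 0 up and 16 down of 41 (adjusted p = 0.127 with an estimated correlation). Histone genes had 10 up and 0 down of 24, antigen presentation genes 4 up and 0 down of 21, NRF2 targets 8 up and 3 down of 24, and endothelial markers 3 up and 0 down of 5 (each at adjusted p = 0.19 with an estimated correlation). Apoptosis regulators had 14 up and 4 down of 28 (adjusted p = 0.127 with an estimated correlation) and TGF-beta and YAP targets 12 up and 6 down of 25 (adjusted p = 0.416 with an estimated correlation). The antigen presentation gene B2M went from 190 to 295 CPM. It lies in a stretch of chromosome 15 that was raised in KO1, with a median of 0.21 after removal of the GC trend. Without genes in shifted stretches the calls of the TGF-beta and YAP (0.07), NRF2 (0.01) and apoptosis (0.18) lists were lost. With limma-voom those of the antigen presentation (0.27), TGF-beta and YAP (0.14), NRF2 (0.03) and endothelial (0.52) lists were lost, and with a filter of at least 1 CPM in 3 libraries those of the TGF-beta and YAP (0.14) and NRF2 (-0.01) lists. Without WT replicate 1 the calls of the TGF-beta and YAP list (median 0.13), the NRF2 list (0.01) and the endothelial list (0.46) were lost. The endothelial call was also lost with a replicate block (0.52) and without WT replicate 2 (0.53), WT replicate 3 (0.55), KO1 replicate 1 (0.53), KO1 replicate 3 (0.54), KO2 replicate 1 (0.52) and KO2 replicate 2 (0.52).

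KO2 was compared with WT to ask what differs in the second clone, in which more genes were called. Among the listed genes, 18 of 24 NRF2 targets and 27 of 40 interferon-stimulated genes rose, and some other genes were nearly silent. FAM133A went from 0.521 to 31.2 CPM, GLUL from 0.791 to 12.1 CPM, and CSF3, which encodes a growth factor of granulocytes, from 1.48 to 13.7 CPM. TNFSF18, a cytokine gene of the TNF family, fell from 19.8 to 0.392 CPM, the long noncoding RNA UCA1 from 47.2 to 4.33 CPM, and ARMCX2 from 63.3 to 3.75 CPM. The cancer-testis gene CT83 had 0 counts in KO2 and 1259 in WT, which makes it at least 343-fold lower against a floor of 3 counts over the group. EEF1A2, which encodes a translation elongation factor, had 3 counts in KO2 and 6122 in WT, a ratio of 1668 in CPM with a counting interval of 570.6 to 8092.

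KO2 had 8776 called genes, 4382 up and 4394 down, and 1731 of these changed at least 2-fold, 1062 up and 669 down. The balance depended on the processing, with 4893 up and 3899 down by upper quartile scaling. After removal of the GC trend 5288 were up and 4417 down, and 3765 and 2607 when genes in shifted stretches were also left out. Other rising genes were FKBP10 (log2 change 3.17), TMEM132D-AS1 (3.08, antisense), RIMS3 (2.84), NPTXR (2.83) and MAMDC2 (2.55). Other falling genes were MYCT1 (-3.24), AC006452.1 (-2.98) and the hyaluronan synthase gene HAS2 (-2.73).

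In KO2, 5 lists were called. NRF2 targets had 18 up, 2 down and 4 not past the threshold of 24 (18 and 2 adjusted over the list alone; median 0.63; adjusted p = 0.0164 with an estimated correlation). Interferon-stimulated genes had 27 up, 8 down and 5 not past the threshold of 40 (29 and 8 adjusted over the list alone; median 0.67; adjusted p = 0.0164 with an estimated correlation). NF-kB targets had 15 up and 6 down of 32 (16 and 7 adjusted over the list alone; median 0.23; adjusted p = 0.158 with an estimated correlation), and 22 up and 7 down after removal of the GC trend (median 0.58). Ribosomal protein genes had 0 up and 37 down of 60, and 38 down adjusted over the list alone. Their median was -0.21 (adjusted p = 0.648 with an estimated correlation). RPL4 fell from 2365 to 873 CPM and lies in a stretch of chromosome 15 that was lower in KO2. That stretch had a median of -0.46 after removal of the GC trend, and RPL4 was at -0.06 in KO1. Mitosis genes had 19 up and 7 down of 32 (19 and 7 adjusted over the list alone; median 0.16; adjusted p = 0.648 with an estimated correlation), with ANLN, which lies in a raised stretch of chromosome 7, at 0.87. This call was lost without WT replicate 2 (median 0.16), without genes in shifted stretches (0.14) and after thinning to the smallest total (0.13). Of leukocyte markers, chosen for naming after their values were seen, CD53 went from 0.142 to 1.32 CPM and LAPTM5 from 9.70 to 33.7 CPM in KO2. PTPRC stood at 0.149 CPM in WT and 0.127 CPM in KO2. After removal of the GC trend the leukocyte list had 3 of 8 tested members up and 0 down in KO2. Its median was 0.54 and it was not called (camera adjusted p = 0.089).

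KO1 was compared with KO2 to test whether the clones differ in their change from WT. They differed in 8679 genes, 4253 higher in KO1 and 4426 higher in KO2, about as many as separated KO2 from WT, and 1812 of these differed at least 2-fold. By upper quartile scaling 3896 were higher in KO1 and 4860 in KO2. ADAMTS9, a metalloprotease gene, was at 6.04 CPM in WT, 19.9 in KO1 and 1.86 in KO2. FRMD3, GLUL and RASEF fell in KO1 and rose in KO2, with log2 differences of -4.87, -6.51 and -6.89. In KO1 the lowest library had 4 counts of GLUL and 5 of RASEF. When single libraries were left out, their differences ran from -6.95 to -6.14 and from -7.31 to -6.66. UCA1, TNFSF18 and MYCT1 rose in KO1 and fell in KO2, with differences of 4.66, 6.57 and 4.25. Of the genes called in KO1 alone, 1613 of 2171 also differed between the clones, as did 3703 of the 4769 called in KO2 alone.

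Of 9 lists called between the clones, the unfolded protein response list, higher in KO1 (16 members higher and 2 lower of 20, median difference 0.31), held with an estimated correlation (adjusted p = 0.0285). Matrix protease genes had 14 members higher in KO1 and 3 lower of 18 (adjusted p = 0.127 with an estimated correlation). Basal markers had 8 higher and 1 lower of 12 (adjusted p = 0.0936 with an estimated correlation), with ITGA6 at a difference of 0.87. Interferon-stimulated genes had 8 higher and 23 lower in KO1 of 40, and NRF2 targets 4 higher and 17 lower of 24 (each at adjusted p = 0.0604 with an estimated correlation). The calls of the mitosis, histone, endothelial and oxidative phosphorylation lists were at adjusted p = 0.523, 0.206, 0.201 and 0.736 with an estimated correlation. The NF-kB list was not called between the clones (adjusted p = 0.102).

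Because the title concerns FANCD2 and replication, the DNA repair and cell cycle lists were examined in each clone. None of the Fanconi anaemia, homologous recombination, ATR-CHK1, G1/S and p53 lists was called against WT by camera, except that the p53 list was called in KO2 without genes in shifted stretches (median 0.23, and 0.30 with the GC trend also removed). The directional fry test called the Fanconi anaemia (-0.06) and p53 (0.16) lists in KO2. Of 28 Fanconi anaemia genes, 6 rose and 8 fell in KO1 (7 and 9 adjusted over the list alone; list adjusted p = 0.796), and 9 rose and 12 fell in KO2 (9 and 12 adjusted over the list alone; list adjusted p = 0.441). In both clones, 2 rose, 4 fell and 6 moved in opposite directions. FANCF was at 0.94 and 0.66, FANCE at -0.47 and -0.38, FAAP100 at -0.66 and -0.91, and FANCA at -0.18 and -0.37. After removal of the GC trend FAAP100 was at -0.31 and -0.44 and FANCE at -0.31 and -0.21, still called. FANCE lies in stretches of chromosome 6 that were lower in both clones, with medians of -0.34 and -0.27 after that removal. TIPIN, whose protein stabilizes replication forks, fell from 57.7 to 21.7 CPM in KO2 and was at 61.3 CPM in KO1. It lies on chromosome 15, which was lower as a whole in KO2. The window of 40 genes with the lowest median in KO2 ran from 59132434 to 66386746 on that chromosome. After removal of the GC trend this window had a median of -1.41, and TIPIN was at -1.46. The cyclin E gene CCNE1 rose by 0.78 in KO2 and was at 0.11 in KO1. CDKN1A, an inhibitor of cyclin-dependent kinases that p53 induces, was at 0.16 and 0.21, and at 0.32 and 0.38 after removal of the GC trend (adjusted p = 7.05e-07 and 3e-08). The KO1 call of FANCA was lost without WT replicate 2 (-0.17) and after removal of the GC trend (-0.08), and that of CDKN1A without WT replicate 1, 2 or 3 (0.17 each), KO1 replicate 1 (0.14) or KO1 replicate 3 (0.16).

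Gene position was examined because long stretches of neighbouring genes moved together, an analysis chosen after the data were seen. Chromosomes and blocks were described by protein-coding genes with a mean log2 CPM of at least 2. In KO2, 92% of the 326 such genes of chromosome 15 were lower than in WT, with a median log2 change of -0.46, while the same chromosome had a median of 0.20 in KO1. Chromosome 18 had medians of -0.40 in KO2 and 0.23 in KO1. A part of chromosome 2 from 169827458 to 241729478 had a median of 0.49 in KO2, and a part of chromosome 14 from 32076114 to 105470729 had a median of -0.25 in KO1. On chromosome 19, genes between 5691834 and 19320844 had a median of -0.77 in KO2, or -0.52 after removal of the GC trend. There were 21 such blocks in each clone. They held 26.3% of the genes called in KO1 and 28.2% of those called in KO2, and 50% and 65.4% of the genes inside were called, against 31.4% and 45.1% of those outside. The blocks of a clone were picked for shifts in the same comparison. A higher share of calls inside them therefore follows in part from that choice. Genes with the highest GC content were also lower in both clones, with medians of -0.29 and -0.35 in the uppermost of 10 equal groups by GC content.

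**Figure D3:**
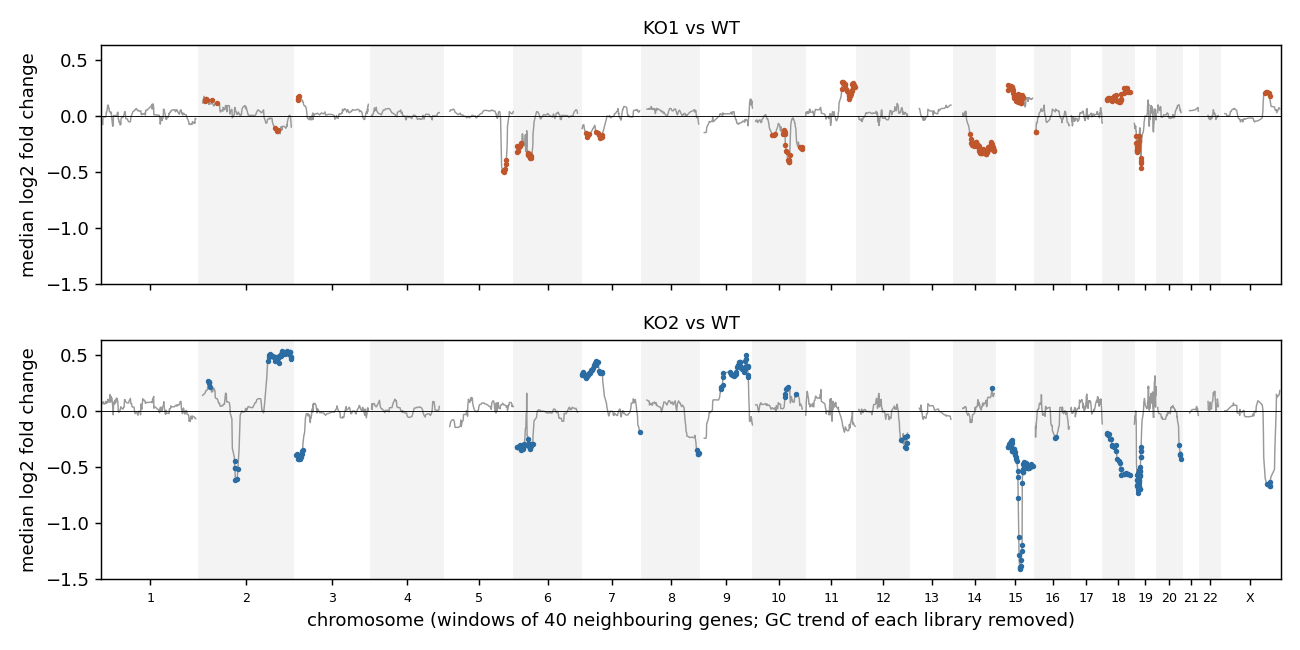
Median log2 change against WT in windows of 40 neighbouring genes along each chromosome, for KO1 (top) and KO2 (bottom), after removal of the GC trend of each library; coloured points are shifted windows. The medians of chromosomes 15 and 18 are -0.46 and -0.41 in KO2 and 0.18 and 0.17 in KO1.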

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

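Results are given here because the clones differ from each other in a direct test, KO1 against KO2; the GC correction, the exclusion of shifted blocks, the tests of chromosome 15 and the comparisons of preparation and of the single control population were chosen only after the result was seen. Of the 91 genes followed in the text, 73 differed at an adjusted p under 0.05, 17 of them with called changes of opposite sign, and 9 gene lists differed by camera. Of all tested genes 48.9% differed between the clones. Many of the 91 genes were named for a large change in a clone or between the clones, which raises the share among them. Differences are log2 values, KO1 minus KO2.

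FBXL12 differed by 0.70 and FANCD2 by 0.42. Among genes that rose in both clones, C15orf48 (1.87), SAP30L-AS1 (1.84), SAA1 (0.93), INHBA (0.81), LCP1 (1.25), AKR1C3 (0.34), OAS3 (0.48), HSPA5 (0.23) and MMP1 (0.90) were higher in KO1. IL1B (-0.20), IL1A (-0.47), BCL2A1 (-0.45), NRCAM (-1.16), SIRPA (-1.19), CXCL3 (-0.52), MAMDC2 (-1.19), OAS2 (-0.79), HERC6 (-0.29), GCLM (-0.39), TXNRD1 (-0.52), SLC7A11 (-0.27), CTSL (-0.43), CD44 (-0.36), LAPTM5 (-1.20), RIMS3 (-2.34) and CSF3 (-2.67) were higher in KO2. Among genes that fell in both, the differences were 1.72 for PGM5, 0.79 for MARCH1, -0.27 for SERPINB9, 0.17 for CPA4, 0.65 for RPS28, -1.97 for FGF13, 0.25 for FAAP100, 0.18 for FANCA, 0.22 for GMNN, 0.19 for RPLP0, 0.18 for RPL10A and -0.17 for BAK1. EEF1A2 was 1155 times higher in KO1 as a ratio of CPM (counting interval 395 to 5604, on 3 counts in KO2). The difference was no longer called for IL1B without KO1 replicate 3 (-0.18) or KO2 replicate 2 (-0.17), or for CPA4 without KO2 replicate 3 (0.15). The same holds for BCL2A1 without KO1 replicate 1 (-0.33), KO1 replicate 3 (-0.42) or KO2 replicate 3 (-0.37), for RPS28 without KO1 replicate 1 (0.57), KO1 replicate 3 (0.68) or KO2 replicate 1 (0.68), and for GMNN without KO2 replicate 3 (0.16). SERPINB9, FAAP100 and BAK1 lost theirs in several such fits, over ranges given with the processing, and FAAP100 also after GC correction (0.13).

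Genes that rose in KO1 and fell in KO2 were ADAMTS9 (3.43), MPZL2 (2.62), TNFSF18 (6.57), UCA1 (4.66), MYCT1 (4.25), AC006452.1 (3.76) and B2M (0.82). Genes that fell in KO1 and rose in KO2 were RASEF (-6.89), ABLIM3 (-4.66), FRMD3 (-4.87), GLUL (-6.51), CCN3 (-2.90), FAM133A (-7.67), FKBP10 (-3.68), TMEM132D-AS1 (-4.07) and TNC (-1.24). GLUL, RASEF and FAM133A had as few as 4, 5 and 6 counts in a KO1 library. The fall of B2M in KO2 was no longer called without WT replicate 1 (-0.14) or KO2 replicate 3 (-0.18). B2M lies in shifted blocks of chromosome 15, with medians of 0.21 in KO1 and -0.46 in KO2 after GC correction. The other genes were LCP2 (1.79), MMP3 (1.63), TENM1 (-3.53), BST2 (-2.09), NPTXR (-2.65), ARMCX2 (4.03), HAS2 (2.73), TIPIN (1.5), CCNE1 (-0.67), HSP90B1 (0.60), ITGA6 (0.87), RPL4 (1.38), ANLN (-0.94), CD53 (-3.72, and -4.40 without KO1 replicate 1) and CSF1R (-1.37). CT83 was at least 409.9-fold higher in KO1, against a floor of 3 counts over the KO2 group. The lists had median differences of -0.18 for mitosis, -0.51 for interferon-stimulated genes, 0.67 for basal markers, 0.52 for matrix proteases, -0.13 for oxidative phosphorylation, 0.31 for the unfolded protein response, -0.49 for NRF2 targets, 0.29 for histones and 0.55 for endothelial markers. Without genes in shifted blocks the calls of the interferon (-0.29), histone (0.33) and oxidative phosphorylation (-0.12) lists were lost. The oxidative phosphorylation call was also lost with size factors of DESeq2 (-0.12), a replicate block (-0.12) or a filter of at least 1 CPM in 3 libraries (-0.15). The same call was lost without WT replicate 1, 2 or 3 (-0.12 each), KO1 replicate 1 (-0.11), KO1 replicate 3 (-0.09), KO2 replicate 1 (-0.10) or KO2 replicate 2 (-0.09). The endothelial call was lost with limma-voom (0.52) and without WT replicate 3 or KO1 replicate 1 (0.65 each).

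Blocks of neighbouring genes moved together, some in opposite directions in the clones, as on chromosome 15, and some alike in both, as on chromosomes 6 and 19. Chromosome 15 was picked for the largest shift of a whole-chromosome median and tested on its 99 protein-coding genes that the block search had not used, with a mean log2 CPM under 2. GC content as the whole cause is argued against by their median in KO2 after the GC trend was removed, -0.52 relative to such genes of all chromosomes (95% interval -0.81 to -0.36), and a few strong genes by the 78.8% that were lower (interval 69.4 to 86.4). A difference in DNA copy number between the clones is a candidate explanation for chromosome 15, since the medians of these genes below and above their median expression were -0.52 and -0.53. The blocks on X (-0.64) and chromosome 19 (-0.52) were shifted more in KO2 than chromosome 15 as a whole, no DNA was measured, and whether such a difference preceded or followed the editing is open.

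Of 32 NF-kB targets and inflammatory cytokine genes, 11 rose in both clones, 1 fell in both and 5 moved in opposite directions, and the KO2 list call was lost with an estimated correlation (adjusted p = 0.158). A GC trend and the shifted blocks as the whole cause are argued against, since the median of the NF-kB list in the average contrast was 0.55 after GC correction and 0.53 without genes in blocks. Leukocytes mixed into KO1 are argued against by PTPRC and CD53, at no more than 0.180 CPM in a KO1 library. In KO2 the bound set beforehand, both genes under 0.5 CPM, was not met: CD53 reached 1.58 CPM and LAPTM5 rose while PTPRC did not, so a few foreign cells cannot be told apart from expression by the cells themselves. The 11 members that rose in each clone may follow loss of FBXL12 or a feature of the one control population, which cannot be told apart because both clones share it.

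Of 60 cytosolic ribosomal protein genes 31 fell in both clones, and the list call was lost with an estimated correlation (adjusted p = 0.236 in KO1, 0.648 in KO2 and 0.293 in the average contrast). A GC trend as the whole cause is argued against by a median of -0.22 after correction. Shared GC content, length and expression are argued against by 10000 random lists matched on these, of which 0% had a median as low (list -0.25, median of the random lists -0.02). A preparation that differed between control and clones cannot be told apart from genotype, since the labels give no batch and only 1 of the 6 clone libraries had a GC slope within the range of WT. The biological explanation, loss of FBXL12, was not tested beyond the clones themselves.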

How the results depend on the processing

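The GC correction and the exclusion of shifted blocks were chosen only after the data were seen; the other alternatives were planned. No result reversed the direction of its test under an alternative where the result was called in either fit; some lists without a call changed direction after GC correction, among them homologous recombination, ATR-CHK1 and G1/S genes in KO2 and cholesterol genes in KO1. With a filter of at least 1 CPM in 3 libraries the medians of the NRF2 list in KO1 (-0.01) and of the matrix proteases in the average (-0.04) lay below 0 and both calls were lost. Apart from fits that leave out a library, 31 gene results lost and 34 gained a call, as did 61 and 96 list results. In fits that leave out 1 library, 53 gene results lost and 20 gained a call, as did 24 and 14 list results. The numbers of called genes were 4690 to 6537 for KO1, 7685 to 9309 for KO2, 5528 to 7606 for the average and 7607 to 8679 for KO1 against KO2, with 1815 to 2955 called in both clones in one direction.

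With both clones pooled as 1 group, whose spread then holds the difference between them, 1858 genes were called. Without genes in shifted blocks, where fewer genes are tested, 3780 were called in KO1, 5579 in KO2, 4658 in the average, 5318 between the clones and 1756 in both. At an adjusted p under 0.01, 3982 were called in KO1. At least 2-fold changes numbered 631 in KO1, 1731 in KO2, 746 in the average and 1812 between the clones. Without a filter on low counts, 8 lists were called in KO2, 16 in the average and 14 between the clones; the cause was not tested. With GC correction and without blocks together, 8 were called in KO2 and 5 between the clones; the cause was not tested. With an estimated correlation, 2 lists were called in KO1, 2 in KO2, 3 in the average and 1 between the clones. The directional fry test, which compares a list with no change and not with other genes, called 23, 22 and 28 in KO2, the average and between the clones.

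After GC correction the calls of CYC1 in both clones and of UQCRC1 in KO2 ended. Leaving out single libraries ended the KO2 calls of C15orf48 (0.39 without WT replicate 2, 0.35 without WT replicate 3, 0.40 without KO2 replicate 1, 0.35 without KO2 replicate 2) and ABLIM3 (0.18 without WT replicate 1), and the KO1 call of CSF3 (0.45 without WT replicate 2, 0.40 without KO1 replicate 1). The difference between the clones ran from -0.22 to -0.10 for BAK1, from 0.17 to 0.38 for FAAP100 and from -0.31 to -0.21 for SERPINB9 over these fits. On simulated counts, with 50 genes changed at each size, 22% of 1.2-fold changes were recovered. In the data 34.8% of tested genes were called in KO1 and 49.4% in KO2. With so many more changed genes the adjusted threshold is less strict, so the simulated share does not measure the sensitivity in the data.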

Other observations

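The comparisons with another group in the place of the control, the GC correction and the exclusion of shifted blocks were chosen only after the result was seen. Some gene lists without a call held changed members; of all tested genes 34.8% were called in KO1 and 49.4% in KO2. Transcripts of the mitochondrial genome had 7 of 13 members up and 0 down in KO2 (median 0.44; list adjusted p = 0.114), and 0 up and 0 down in KO1. Collagen and matrix genes had 9 up and 7 down of 24 in KO2, and cholesterol synthesis genes 7 up and 8 down of 23. Glycolysis genes had 2 up and 4 down of 18 in KO1 and 4 up and 5 down in KO2. With all libraries and the preset correlation these lists were not called by camera in either clone, but some alternatives called them. The mitochondrial list was called in KO2 with limma-voom (0.44), without a filter on low counts (0.43), and without KO1 replicate 2 (0.44) or KO2 replicate 3 (0.48). The collagen list was called in KO1 after GC correction (0.22), and in KO1 (0.22) and KO2 (0.43) when genes in shifted blocks were also left out. The directional fry test called the mitochondrial, collagen and cholesterol lists in KO2 (0.44, 0.11 and -0.01).

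The libraries were also regrouped to ask how often other splits give results as large. Splits of 3 libraries against 3 number 10, too few for a share under 0.05. KO1 against WT gave 6178 genes (the highest other split 0), KO2 against WT 8776 (0) and KO1 against KO2 8679 (0), each reached by 1 split. For gene lists, 2 of 10 splits reached the 13 of KO1 against WT (highest other 13), 4 of 10 reached the 5 of KO2 against WT (highest other 5), and 1 of 10 reached the 9 of KO1 against KO2 (highest other 5). Over 60 drawn splits of all 9 libraries, 1 reached the 7243 genes of the average contrast (highest other 2026). Also, 1 reached the 2674 genes called in both clones (highest other 473). The other splits drawn mixed libraries of different groups, which puts the differences between groups into the spread and lowers the calls. These counts therefore show only that libraries of a group resemble each other. Exchanges of whole groups, given below, were not among the splits drawn. For the 10 lists of the average contrast, 4 of 60 splits called as many and the highest other called 16. These splits mixed libraries of different groups and may keep part of the differences between groups. They therefore cannot decide whether a chance split would give as many lists, which is not excluded.

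The counts do not single out the control among the groups. With KO1 in the place of the reference, 7382 genes were called in the average contrast and 3225 in both others in one direction; with KO2 these were 9250 and 5800. WT as the reference gave 7243 and 2674. Each group set against the other 2 thus gave as many genes or more.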
